A study of Mus musculus with 48 samples.

How the data were processed

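The study sequenced total RNA of individual placentas of mouse embryos matched by somite number, per the labels, with 4 placentas in each of 12 groups (48 libraries, 2 of each sex in every group). The embryos were F1 hybrids of the 129S1 and JF1 strains, from a 129S1 mother or from a JF1 mother. The groups were homozygous Ehmt2 mutants and their wild-type siblings (6 somites in either cross, 12 somites with a JF1 mother), embryos from oocytes that lacked Ehmt2 and their controls from floxed mothers without the Cre driver, wild-type embryos of a heterozygous mother or of a heterozygous father, and embryos of the unmodified control lines in either cross. Only the SET domain of Ehmt2 was deleted, per the labels, so a gene-level count does not check the genotype. Ages at collection differed between groups and within the maternal mutants, per the labels. Wild-type siblings here means wild-type embryos of heterozygous parents, matched by somite number and not by litter. In each homozygous comparison they were collected at an earlier age than the homozygous embryos, per the labels.

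The authors made stranded, ribosomal-RNA-depleted libraries and sequenced them as paired 75-base reads on 5 flowcells, per the labels. The deposited gene-level table holds raw counts from featureCounts 1.6.1 on the Ensembl GRCm38.82 annotation (mm10). Per the file headers, counting was stranded, took primary alignments with a mapping quality of at least 20, ignored duplicates, and counted each read of a pair singly. The deposited file of allele-level values holds raw counts of reads assigned to the 129S1 or to the JF1 genome, per the labels. The submitters' processing notes name STAR 2.6.0c, HISAT2 2.1.0, SAMtools 1.9, deepTools 3.2.1 and Cufflinks without a version. The gene table holds 46517 genes, of which 46005 (98.9%) took a symbol from the annotation, and the allele table holds 46603 genes. Coordinates below are mm10.

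Each placenta gave 20955057 to 29473608 gene-level counts over 23574 to 28430 detected genes, and 4557685 to 6193380 allele-assigned reads (20.0% to 22.9%). A set of 3 rRNA-like genes (Gm26917, Gm42418 and CT010467.1) took 8.9% to 18.7% of the counts. When a 4-fold change was written into simulated copies of the counts, 96.6% of the changed genes were recovered in the 6-somite homozygous comparison of the 129S1-mother cross and 81.5% in the maternal mutant comparison. At 2-fold these values were 58.5% and 24.2%, and at 1.5-fold 28.4% and 2.99%. The false share among calls in these tests on simulated data ran from 1.39% to 10.6%.

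Samples were grouped by their characteristics fields. The maternal controls carry titles that name them mutant, and their descriptions and characteristics, which name them controls, were followed. For 2 control-line libraries of the JF1-mother cross the characteristic and another field of the labels give opposite sexes, and Y-linked and Xist counts fit the characteristic. The 12 comparisons were the homozygous groups against wild-type siblings (3), maternal mutants against maternal controls, embryos of a heterozygous mother or father against the control line (2), wild-type siblings and maternal controls against control lines (3), 12 against 6 somites in wild-type and in homozygous placentas (2), and the control lines of the 2 crosses. A pair of interactions tested whether the homozygous effect differed by stage or by cross.

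Differential expression used edgeR 4.0.16 in R 4.3.3 (TMM factors, filterByExpr, glmQLFit and glmQLFTest with default settings, two-sided), with one fit per comparison and a Benjamini-Hochberg adjusted p below 0.05 as the threshold. Fold changes are given as log2 values with standard errors, and levels as mean CPM with the SD over placentas. Where a group held no counts the fold is given as a lower bound at 3 counts over the group, and where it held 1 to 3 counts as a ratio with a counting interval of 95%. Such intervals cover counting error only. The 29 gene lists, written before the data were examined, were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) at a preset correlation of 0.01 and again with the estimated correlation. Beside the counts over all genes, list members were also adjusted over the list alone. The low-count filter was applied per comparison, so a gene silent in a group was measured only where the other expressed it. For lists of normally silent genes the counts risen and fallen, medians and camera p are thus partly set by the filter. DESeq2 1.42.0 served as the second tool.

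For allele counts, genes with a mean of at least 20 allele reads per library were tested on the share of one allele with edgeR (two-sided), each library contributing its 2 alleles. Parent-of-origin and strain effects were separated by comparing the 2 control crosses, and genes past the threshold were called biased where the share averaged over the crosses was at least 70% or at most 30% (for parent of origin also on the same side of 50% in each cross). Change of the maternal share was tested in the 6 genotype comparisons, leaving out the genes of the 129S1 interval that, per the labels, surrounds Ehmt2 in the JF1 line. The maternal share over all autosomal allele counts was compared by exact two-sided permutation of 4 against 4 placentas, whose smallest possible p is 0.0286.

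The rule for named genes was also fixed before the data were examined. It takes Ehmt2 always, the 10 largest rises and the 10 largest falls per comparison among genes past the threshold with a mean log2 CPM of at least 1, group ranges that do not overlap and a symbol that is not a predicted-gene name, and up to 4 members of each list with the smallest adjusted p. For allele tests it takes every imprinted list member with enough reads, the 5 most maternal and the 5 most paternal genes outside the lists, and the 5 largest share changes per comparison. Genes named outside this rule are said to be chosen after their values were seen.

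The alternatives tried were DESeq2 size factors, the DESeq2 Wald test, no low-count filter, all 48 libraries in one fit, a sex covariate, a replicate block, each library left out, a minimum of 50 allele reads, logit shares in limma, autosomal genes alone, and the estimated correlation for lists. Others were chosen after seeing the data: without the 3 rRNA-like genes, the control line as reference, males alone, without maternal mutant replicates 2 and 4, centred logit shares, and without the part of chromosome 17 next to Ehmt2. All 48 libraries and all columns of the deposited tables were used. Tables were assembled with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and the R package data.table (version 1.17.8), and figures with matplotlib 3.10.9.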

Results

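Ehmt2 encodes the H3K9 methyltransferase G9a, and its deletion removed only the SET domain, so its gene-level count (chr17:34898469-34914052, GRCm38) does not check the labels. At 6 somites homozygous placentas held 165.5 ± 7.18 CPM of Ehmt2 against 168.7 ± 7.95 CPM in wild-type siblings with a 129S1 mother (mean ± SD, n = 4 placentas per group here and throughout). The values were 154.3 ± 6.46 against 163.7 ± 20.1 CPM with a JF1 mother, and neither difference passed (edgeR adjusted p = 0.88 and 0.58). At 12 somites Ehmt2 fell, from 154.3 ± 9.08 to 129.2 ± 3.86 CPM (log2 fold change -0.21 ± 0.06 SE, edgeR, two-sided, adjusted p = 0.017). Placentas of oocyte-deleted mothers held 150.3 ± 31.7 CPM against 178.7 ± 2.13 CPM in their controls, a difference that did not pass (adjusted p = 0.41). Depth ran from 20955057 to 29473608 counts per placenta. Each placenta is a separate embryo, and counting intervals below cover counting error only.

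In the 6-somite homozygous placentas of the 129S1-mother cross, genes normally silent outside the germline were switched on. These placentas were collected at a later age than their siblings, per the labels. The cancer-testis antigen gene Magea8 (chrX:154985775-154995850) went from no counts in wild-type siblings to 29.9 CPM, at least 1040-fold, and its relative Magea3 rose at least 443-fold. Asz1, which protects germ cells from transposons, rose from 0.454 CPM with a log2 of 7.82 ± 0.23 (adjusted p = 1.1e-07). Among wild-type siblings with 1 to 3 counts, the ratio was 3190 for Magea5 (counting interval 573 to 126000), 2830 for Pet2 (507 to 112000), 1570 for Magea10 (282 to 62100), 607 for Magea6 (109 to 24000) and 446 for Igbp1b (80 to 17600). The RNA export factor gene Nxf3 (log2 8.42 ± 0.33), the autophagy-related Wdfy4 (log2 8.26 ± 0.21) and Wfdc15a (log2 8.03 ± 0.33), whose product is a protease inhibitor, completed the 10 largest rises. Members of the Magea family are near-identical, so the share of each is uncertain. In all, edgeR called 4159 of 18117 genes (two-sided), 2183 up and 1976 down, and 736 rose and 772 fell at least 2-fold. Magea8 varied between placentas, with 1.18 CPM in replicate 1 of the homozygous group.

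The largest falls in that cross were in genes of the allantois and of blood vessels. The limb and allantois transcription factor gene Tbx4 fell from 30 to 1.46 CPM (log2 -4.35 ± 0.87, adjusted p = 0.0057), and Hoxa9 fell with a log2 of -4.67 ± 0.68. The tight-junction gene Cldn5 of endothelium fell from 7.86 to 0.364 CPM (log2 -4.41 ± 0.56). Of the allantois and extraembryonic mesoderm list, 9 of 13 measured genes fell and none rose (10 adjusted over the list alone), among them Hoxa13 (log2 -3.03 ± 0.40) and Tbx2 (log2 -2.80 ± 0.42). Camera gave an adjusted p of 1.0e-05, and 0.463 with an estimated correlation. Of the endothelium list 8 of 12 fell (8 adjusted over the list alone), including Emcn (log2 -4.21 ± 0.69), Robo4 (log2 -4.14 ± 0.53) and Sox18 (log2 -2.91 ± 0.43). The list as a whole passed at 1.5e-05 by camera, but lay at 0.342 with an estimated correlation. The other large falls included the Wnt antagonist Sfrp1 (log2 -3.98 ± 0.63), the cardiac regulator Gata5 (log2 -3.92 ± 0.70) and the endothelial receptor Adgrl4 (log2 -3.88 ± 0.59). Also among them were the matrix gene Tnc (log2 -3.82 ± 0.47), the mesenchymal regulator Twist1 (log2 -3.71 ± 0.65), Cd34 (log2 -3.60 ± 0.58) and the vascular factor Fli1 (log2 -3.57 ± 0.56). Markers of maternal tissue moved with this group: all 3 measured genes of maternal blood rose (3 adjusted over the list alone), among them Hbb-bs (log2 2.22 ± 0.42) and the neutrophil gene Ltf (log2 2.08 ± 0.33). For the list camera gave 0.0071, and 0.328 with an estimated correlation.

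Germline genes and noncanonical imprinted genes rose in the same placentas, while canonical imprinted genes moved in both directions. Of 25 measured germline and meiosis genes 13 rose and none fell (18 adjusted over the list alone), including Rpl10l (log2 4.49 ± 0.19) and the piRNA gene Piwil2 (log2 2.21 ± 0.11). In siblings against the control line 18 of this list were measured. Some of the 25 may thus enter only through homozygous expression. The adjusted camera p was 2.0e-11, and 0.064 with an estimated correlation. All 7 genes of the noncanonical imprinted list rose (7 adjusted over the list alone), with a median log2 of 0.77. Among them were Smoc1 (log2 1.00 ± 0.09), the repressor gene Sfmbt2 (log2 0.83 ± 0.05), Jade1 (log2 0.77 ± 0.07) and the signalling adaptor Gab1 (log2 0.60 ± 0.07). Tested together, they reached 9.2e-06 by camera and 0.188 with an estimated correlation. Of the maternally expressed imprinted genes 4 of 33 rose and 11 fell (5 and 11 adjusted over the list alone). Th was up (log2 2.86 ± 0.19), while Pon3 (log2 -2.74 ± 0.29) and Pon2 (log2 -1.25 ± 0.08) were down. This list did not pass as a group (camera 0.239, and 0.769 with an estimated correlation). Of the paternally expressed ones 2 of 27 rose and 10 fell (3 and 10 adjusted over the list alone), including the growth gene Mest (log2 -1.89 ± 0.29) and Magel2 (log2 -2.35 ± 0.40). As a group they stood at 0.0404 by camera, and at 0.554 with an estimated correlation.

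Stress and metabolic lists also moved in that cross. Of the hypoxia and glycolysis list 13 of 18 genes rose and none fell (14 adjusted over the list alone), for example Hk2 (log2 0.86 ± 0.14) and the glucose transporter Slc2a1 (log2 0.74 ± 0.09). The camera test put the group at 9.2e-06, and at 0.5 with an estimated correlation. Of the p53 targets 9 of 14 rose and 1 fell (11 and 1 adjusted over the list alone), with Eda2r (log2 2.36 ± 0.24) and the cell-cycle inhibitor Cdkn1a (log2 1.65 ± 0.19) up and Plk2 (log2 -0.77 ± 0.10) down. Camera gave an adjusted p of 0.00013, and 0.354 with an estimated correlation. The parietal endoderm list fell as a group (0.0177, and 0.5 with an estimated correlation), though none of its 12 genes was called alone. Called up and down were 3 and 6 of 21 for the H3K9 and DNA methylation machinery (Tet3 up, log2 0.26 ± 0.05; Trim28 down, log2 -0.21 ± 0.04), 3 and 0 of 17 for Polycomb and 0 and 2 of 15 for giant cells. They were 3 and 5 of 17 for labyrinth (Esx1 down, log2 -1.63 ± 0.22), 2 and 1 of 15 for trophoblast stem cells, and 2 and 4 of 16 for decidua, whose median (0.06) and mean (-0.13) differ in sign. The same counts were 2 and 0 of 5 for the two-cell list, 1 and 0 of 4 for uterine natural killer cells, 2 and 0 of 12 for erythroid genes and 0 and 1 of 4 for macrophages. Proliferation had 1 and 1 of 16, interferon response 2 and 1 of 10, the unfolded protein response 3 and 0 of 12, cholesterol synthesis 1 and 0 of 15 and nutrient transporters 5 and 1 of 16. None was called among 7 spongiotrophoblast, 11 visceral endoderm (median up, test down) and 8 X inactivation and Y-linked genes. No clustered protocadherin beta gene of the 22 in the table was expressed enough to test, here or in any comparison.

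With a JF1 mother, 6-somite homozygous placentas also switched on germline genes. Magea8 rose at least 396-fold and Magea3 at least 299-fold over siblings without a count. Pet2 reached a ratio of 5010 (900 to 198000), Magea5 of 1740 (312 to 68800), and Magea10 of 1180 (328 to 9780). The ratio was 1060 for Pramel3 (190 to 41900), 398 for Magea2 (71.4 to 15700) and 261 for the phosphatase gene Ptprq (72.3 to 2160). Asz1 rose from 0.795 to 108 CPM (log2 7.03 ± 0.48). Nxf3 rose from 0.0424 to 26.6 CPM (log2 9.08 ± 0.42), and Wfdc15a with a log2 of 8.16 ± 0.42. edgeR called 2212 of 17825 genes (two-sided), 1383 up and 829 down. Of these 805 rose and 206 fell at least 2-fold. The count was 4391 with all 48 libraries in 1 fit, 5874 with the control line as reference, 900 with the replicate block and 1373 without homozygous replicate 3. Per the labels the siblings were collected at 8 dpc and the homozygous placentas at 8.7 dpc, and these siblings differed from the control line in 893 genes. The largest falls were smaller than those of the other cross: the kinase gene Stk26 (log2 -2.17 ± 0.46), the hormone gene Stc2 (15.4 to 3.48 CPM, log2 -2.15 ± 0.38), and the channel Trpm2 (log2 -2.04 ± 0.31). Next came the glycolytic regulator Pfkfb3 (33.7 to 8.39 CPM, log2 -2.01 ± 0.30), Efna3 and Ak1 (log2 -1.93 ± 0.37). The remaining ones were Nexmif (log2 -1.79 ± 0.26), L1cam (log2 -1.78 ± 0.21), Adamts3 (log2 -1.76 ± 0.30) and Gtsf1l (log2 -1.76 ± 0.32).

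Germline and meiosis genes rose in 17 of 27 measured cases and fell in none (18 adjusted over the list alone), Sycp2 among them (log2 2.93 ± 0.24). In siblings against the control line 20 were measured. For the list camera gave 2.5e-12, and 0.0429 with an estimated correlation. Of the noncanonical imprinted genes 6 of 7 rose (6 adjusted over the list alone), for example Smoc1 (log2 0.92 ± 0.08) and Slc38a4 (log2 0.71 ± 0.10). For the list camera gave 1.2e-06, and 0.0429 with an estimated correlation. Of the two-cell list 3 of 6 rose (5 adjusted over the list alone), among them Sp110 (log2 3.09 ± 0.49). The adjusted camera p was 0.0013, and 0.0967 with an estimated correlation. p53 targets rose in 8 of 14 cases (8 up and 1 down adjusted over the list alone), with Eda2r (log2 3.08 ± 0.27) and Cdkn1a (log2 2.19 ± 0.28) ahead. Tested together, they reached 0.00017 by camera and 0.333 with an estimated correlation. Hypoxia genes fell here in 6 of 18 cases (9 adjusted over the list alone), among them Eno1 (log2 -0.78 ± 0.14) and Pgk1 (log2 -0.72 ± 0.16). As a group they stood at 0.00079 by camera, and at 0.81 with an estimated correlation. In the siblings that serve as reference, 2 of 18 hypoxia genes (6 adjusted over the list alone) were in turn higher than in the control line (1.3e-05, and 0.478 with an estimated correlation). Interferon genes fell in 5 of 10 cases (1 up and 6 down adjusted over the list alone), led by the sensor Ifih1 (log2 -3.01 ± 0.49) and Bst2 (log2 -1.43 ± 0.12). The camera test put the group at 0.0045, and at 0.565 with an estimated correlation. In the reference siblings 3 of 8 interferon genes (6 adjusted over the list alone) were in turn higher than in the control line. Camera gave 0.00011 there, and 0.393 with an estimated correlation. Trophoblast stem cell genes fell in 6 of 15 cases (8 adjusted over the list alone), including Sox2 (log2 -1.74 ± 0.29) and Eomes (log2 -1.35 ± 0.30). Camera gave an adjusted p of 0.00079, and 0.322 with an estimated correlation. Proliferation genes fell in 3 of 16 cases (5 adjusted over the list alone), for example Aurka (log2 -0.48). The list as a whole passed at 0.00058 by camera, but lay at 0.784 with an estimated correlation.

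Maternal blood markers moved with this group too, 3 of 4 rising (4 adjusted over the list alone), with Ltf at log2 2.73 ± 0.41 and Hbb-bs at log2 2.50 ± 0.51. For the list camera gave 0.002, and 0.23 with an estimated correlation. Among maternally expressed imprinted genes 8 of 33 rose and 4 fell (9 and 4 adjusted over the list alone), Tfpi2 up (log2 4.00 ± 0.75) and Pon2 down (log2 -0.88 ± 0.10), with a median below 0 and a mean above it. Of the paternally expressed ones 4 of 27 rose and 1, Peg12, fell (log2 -1.74 ± 0.20; 5 and 1 adjusted over the list alone). Called up and down were 2 and 4 of 21 for H3K9 and DNA methylation machinery (Dnmt3b, log2 -0.49 ± 0.10), 1 and 0 of 17 for Polycomb and 1 and 0 of 15 for giant cells (Prl7a1, log2 3.06 ± 0.72). Labyrinth had 2 and 4 of 17 (median up, test down) and decidua 3 and 0 of 14 (Htra3, log2 3.28 ± 0.75). They were 1 and 0 of 5 for natural killer cells (Il2rb, log2 1.45 ± 0.24) and for macrophages, and 3 and 0 of 8 for erythroid genes (Hbb-y, log2 5.56 ± 1.17). Parietal endoderm had 1 and 0 of 12, and allantois 1 and 1 of 13 (median up, mean down). They were 1 and 1 of 12 for unfolded protein response and 2 and 0 of 16 for nutrient transporters (median down, test up). None was called among spongiotrophoblast, visceral endoderm, endothelium, cholesterol synthesis and X and Y genes, the last with a median and a mean of opposite sign.

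At 12 somites, homozygous placentas expressed genes of the two-cell embryo along with the germline genes. Per the labels they were collected at 9.5 dpc and their siblings, at the same somite number, at 8.7 dpc. Pet2 rose to 43.7 CPM from none in siblings, at least 1500-fold. Against siblings without a count, Magea10 rose at least 697-fold, Zfp352 at least 435-fold, Magea5 at least 433-fold and Magea8 at least 357-fold. Under the same bound Pramel3 rose at least 285-fold, Magea3 at least 243-fold, the near-identical deubiquitinase genes Usp17lc at least 237-fold and Usp17lb at least 218-fold, and Trim52 at least 196-fold. Of the two-cell list 12 of 15 genes rose and 1 fell (12 and 1 adjusted over the list alone). Among them were Zscan4d (at least 118-fold), Tdpoz4 (ratio 1050, 188 to 41400) and Sp110 (log2 6.06 ± 0.56). Their median log2 was 7.82, and 6.14 with genes without counts at their bound. In 8 of the 15 genes a group held no counts, so these could change only toward the other group. The adjusted camera p was 2.2e-08, and 0.373 with an estimated correlation. In the test of the difference between stages none of 18 two-cell genes was called, and the list reached 7.9e-05 by camera, higher at 12 somites, and 0.66 with an estimated correlation. Asz1 rose from 0.825 to 77.5 CPM (log2 6.61 ± 0.37) and the germ-cell RNA binder Dazl with a log2 of 3.89 ± 0.27. In all 21 of 24 germline genes rose (21 adjusted over the list alone). Tested together, they reached 4.1e-12 by camera and 0.0378 with an estimated correlation. edgeR called 5802 of 18712 genes (two-sided), 3146 up and 2656 down. Of these 1370 rose and 118 fell at least 2-fold. Prl2b1, a placental hormone gene of a near-identical family, fell from 21 to 0.795 CPM (log2 -4.72 ± 0.98). The next falls were Efna3 (log2 -1.96 ± 0.27), the heat-shock genes Hspa1a (log2 -1.95 ± 0.35) and Hspa1b (log2 -1.73 ± 0.26), and Tcfl5 (log2 -1.94 ± 0.18). They were followed by Ptprd (log2 -1.82 ± 0.28), Pou3f1 (log2 -1.71 ± 0.14), Col25a1 (log2 -1.57 ± 0.33), Gtsf1l (log2 -1.51 ± 0.16) and Lix1 (log2 -1.51 ± 0.35).

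Erythroid genes rose in 11 of 13 cases at 12 somites (12 adjusted over the list alone), including Gypa (log2 4.74 ± 0.76) and Hba-a2 (log2 3.97 ± 0.73). As a group they stood at 0.00011 by camera, and at 0.555 with an estimated correlation. Cholesterol synthesis genes rose in 14 of 15 (14 adjusted over the list alone), for example Insig1 (log2 0.91 ± 0.11) and Fdft1 (log2 0.71 ± 0.08). The camera test put the group at 4.0e-06, and at 0.373 with an estimated correlation. p53 targets rose in 9 of 14 (13 adjusted over the list alone), with Eda2r (log2 2.37 ± 0.15) and Cdkn1a (log2 2.18 ± 0.11) again. Camera gave an adjusted p of 2.9e-06, and 0.197 with an estimated correlation. Noncanonical imprinted genes rose in 6 of 7 (6 adjusted over the list alone), Smoc1 with a log2 of 0.98 ± 0.07. The list as a whole passed at 0.00051 by camera, but lay at 0.302 with an estimated correlation. Nutrient transporters rose in 6 of 16 (6 adjusted over the list alone; Slc40a1, log2 0.99 ± 0.09). For the list camera gave 0.0107, and 0.385 with an estimated correlation. Paternally expressed imprinted genes rose in 8 and fell in 3 of 28 (10 and 3 adjusted over the list alone; Dio3, log2 1.70 ± 0.12). For the list camera gave 0.0353, and 0.707 with an estimated correlation. Proliferation genes fell in 7 of 16 (11 adjusted over the list alone), for example Mcm5 (log2 -0.31 ± 0.05). The adjusted camera p was 0.0032, and 0.555 with an estimated correlation.

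Maternally expressed imprinted genes rose in 8 of 33 and fell in 2 (8 and 2 adjusted over the list alone), Slc22a18 with a log2 of 1.58 ± 0.09. Decidua markers moved with the 12-somite group, 6 of 16 rising and none falling (6 adjusted over the list alone; Dcn, log2 1.69 ± 0.26; Htra3, log2 2.24 ± 0.27). Called up and down were 3 and 7 of 21 for H3K9 and DNA methylation machinery (Trim28, log2 -0.44 ± 0.07), 4 and 5 of 17 for Polycomb and 0 and 4 of 17 for giant cells (Prl3d1, log2 -2.06 ± 0.56). Labyrinth had 8 and 5 of 17 (Gcm1, log2 0.99 ± 0.11; Wnt7b, log2 -1.10 ± 0.13), and trophoblast stem cells 1 and 4 of 15 (Sox2, log2 -2.27 ± 0.41). They were 3 and 1 of 10 for interferon response (Mx1, log2 3.65 ± 0.67) and 4 and 4 of 18 for hypoxia (Vegfa, log2 0.90 ± 0.09; Eno1, log2 -0.40). Natural killer cells and maternal blood had 1 and 0 of 4 each, macrophages 2 and 0 of 4, and visceral endoderm 2 and 0 of 13 (Afp, log2 2.90 ± 0.22). They were 6 and 0 of 12 for parietal endoderm, 3 and 2 of 14 for allantois, 1 and 0 of 12 for endothelium and 2 and 4 of 13 for unfolded protein response. None of 9 spongiotrophoblast genes or of 8 X and Y genes was called, the latter with a median above 0 and a test below it.

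The homozygous groups shared 638 rises and 223 falls among 17244 genes tested in all 3 comparisons. Between the 6-somite crosses 789 rises were shared against 159.2 by chance, and 374 falls against 86.8. Besides the germline genes, the labyrinth regulator Esx1 fell in all 3 (log2 -1.63 ± 0.22, -1.26 ± 0.24 and -1.35 ± 0.14), as did the retroviral restriction gene Fv1 (-1.36, -1.30 and -1.17), which was chosen after its values were seen. The panels per placenta show these genes together with Peg12.

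**Figure D1:**
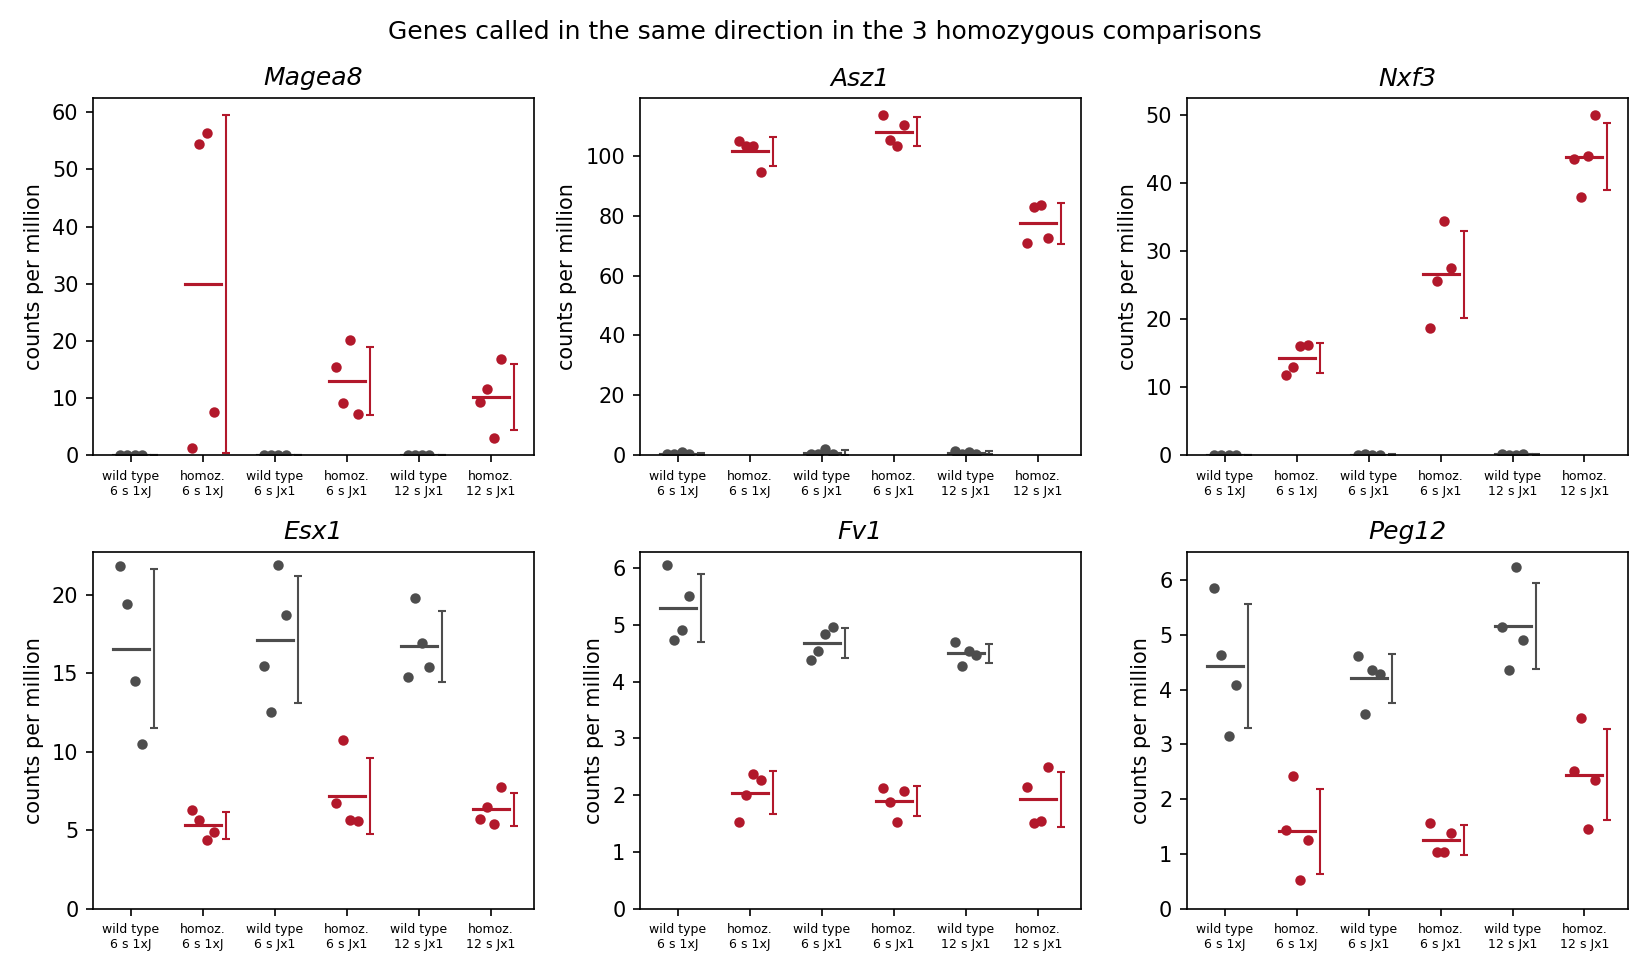
CPM per placenta of Magea8, Asz1, Nxf3, Esx1, Fv1 and Peg12 in homozygous and wild-type groups. Points are placentas, lines are means and bars are SD.

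The homozygous effect differed by cross for 519 of 19147 genes by the edgeR interaction test (two-sided), 174 higher and 345 lower with a 129S1 mother. It was 575 with the control lines as reference and 330 with the replicate block, and ran from 207 (129S1-mother wild type 1 out) to 648 with 1 library left out. The low counts came without 129S1-mother wild type 1 to 3 (207, 212, 329), JF1-mother wild type 2 (301), 129S1-mother homozygous 1 (309) or 3 (243), or JF1-mother homozygous 3 (249). The wild-type siblings of the JF1-mother cross in this test are those that differed from their control line in 893 genes. The gap-junction gene Gjb2 fell from 148 to 48.3 CPM with a 129S1 mother and rose from 10.2 to 73.7 CPM with a JF1 mother (interaction log2 -4.46 ± 0.62), and Gabrp moved likewise (log2 -4.71 ± 0.67). Lncenc1 (log2 4.31 ± 0.29), the lymphoid-related X-linked gene Xlr5c (log2 3.66 ± 0.36), Duox2 (log2 3.15 ± 0.50), Stc2 (log2 2.76 ± 0.47) and Pfkfb3 (log2 2.68 ± 0.44) differed the other way. Emcn (log2 -6.14 ± 1.13), Robo4 (log2 -4.76 ± 1.13) and Tnc (log2 -4.32 ± 0.88) were lower. Hypoxia genes were called in 10 of 18 cases (15 adjusted over the list alone), all higher. The adjusted camera p was 2.6e-13, and 0.292 with an estimated correlation. Lower were 2 of 12 endothelium genes (8 adjusted over the list alone). Tested together, they reached 2.1e-06 by camera and 0.292 with an estimated correlation. By stage, 69 of 19628 genes differed, 50 higher and 19 lower at 12 somites. DESeq2 gave 522 and the replicate block 29, and with 1 library left out the count ran from 6 (12-somite wild type 2 out) to 160 (6-somite wild type 3 out), within 1.5 times of 69 in only 2 of 16 cases. Parp10 (log2 2.54 ± 0.38), Cyp2s1 (log2 2.51 ± 0.51), Pfkfb3 (log2 2.48 ± 0.40) and the interferon sensor Ifih1 (log2 3.70 ± 0.61) were higher. Sdr9c7 (log2 -3.78 ± 0.71), Banp (log2 -2.04 ± 0.20), Grap (log2 -1.80) and the chaperone genes Dnajb1 (log2 -0.83 ± 0.12) and Hspa8 (log2 -0.64 ± 0.12) were lower. The interferon list had 1 of 12 called (4 adjusted over the list alone). As a group they stood at 1.8e-06 by camera, and at 0.0933 with an estimated correlation. The 6-somite wild types of this test are the JF1-mother siblings, in which interferon genes were higher than in the control line.

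From 6 to 12 somites, wild-type placentas gained vessel and allantois genes and embryonic globin RNA. The 6-somite placentas here are the JF1-mother siblings, collected at 8 dpc per the labels, which differed from their control line in 893 genes. Against that line 12 of their 13 allantois genes were lower and 6 of 18 hypoxia genes higher, each adjusted over the list alone. The embryonic globin gene Hbb-y rose from 0.170 to 14.3 CPM (log2 6.39 ± 1.23). The endothelial gene Emcn rose with a log2 of 5.51 ± 0.44, Cygb 5.23 ± 0.57, Hba-x 5.08 ± 1.11 and the mesenchymal RNA Dnm3os 4.85 ± 0.28. The vasoactive peptide gene Adm fell from 297 to 75.1 CPM (log2 -1.99 ± 0.30), with Rgs11 (log2 -2.20 ± 0.23), Nat8l (log2 -2.18 ± 0.33), Sox2 (log2 -2.17 ± 0.31) and Bnip3 (log2 -1.90 ± 0.21). edgeR called 2460 of 17814 genes (two-sided), 1702 up and 758 down, and 1563 without 12-somite replicate 4. Allantois genes rose in 13 of 14 cases (14 adjusted over the list alone). Tested together, they reached 2.2e-11 by camera and 0.306 with an estimated correlation. Endothelium genes rose in 7 of 12 (8 adjusted over the list alone). As a group they stood at 1.1e-05 by camera, and at 0.333 with an estimated correlation. Embryonic erythroid genes rose in 5 of 9 and fell in 1 (5 and 1 adjusted over the list alone; 0.0229, and 0.487 with an estimated correlation). Paternally expressed imprinted genes rose in 14 of 27 (15 adjusted over the list alone). The camera test put the group at 1.4e-07, and at 0.266 with an estimated correlation. Hypoxia genes fell in 16 of 18 (16 adjusted over the list alone). The camera test put the group at 2.2e-11, and at 0.266 with an estimated correlation. Trophoblast stem cell genes fell in 10 of 15, Elf5 among them (log2 -1.18 ± 0.15). Camera gave an adjusted p of 4.4e-05, and 0.266 with an estimated correlation. Homozygous placentas changed in 4993 of 18698 genes over the same interval, 2905 up and 2088 down. Hbb-y (log2 5.60), Slc4a1 (log2 4.99) and the caveolar gene Cav1 (log2 4.99) rose, and Adm fell (log2 -3.21). All 13 allantois genes rose (13 adjusted over the list alone; 1.0e-06, and 0.688 with an estimated correlation). Lars2 also fell (log2 -4.10) with 339 ± 510 CPM at 6 somites, so that few placentas carry it, and it overlaps rRNA-like sequence. The genotypes shared 1287 rises against 251 by chance and 310 falls against 88.9.

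In control placentas 509 of 11507 genes with allele reads had parent-of-origin bias (edgeR, two-sided), 448 maternal and 61 paternal. Of these 371 lie on the X chromosome, 26 in the mitochondrial genome and 112 on autosomes (51 maternal and 61 paternal). Sfmbt2 was paternal almost entirely, with a maternal share of 0.435% and 0.399% in the control crosses, while Gab1 was at 26.3% and 21.4%. Of the noncanonical list 5 of 6 measured genes were called paternal (median maternal share 16.7%). Of the maternally expressed list 19 of 25 were maternal (92.6%), and of the paternally expressed list 15 of 18 paternal and 1, Rtl1, maternal (94.1% and 90.6%), a gene with an antisense transcript. Platr4, Nap1l4, H13, Ddc, Ube3a, Copg2, Phactr2, Mcts2 and Dio3 were not called. Of the 61 paternal autosomal genes, 32 lie inside Sfmbt2 (chr2:10370510-10595253), many of them short RNAs such as Mir466f-1 and Mir669e, so these count as 1 locus. The most maternal genes outside the lists, Gm10222, Gm28438, Gm10925, Gm29216 and Gm28437, resemble mitochondrial sequence. The 51 maternal autosomal genes are also fewer loci, by examples chosen after their values were seen. Gm28439 and Gm28661 lie beside those just named, Gm27483 and Gm27786 inside H19, and Gm26945 and Gm37899 between Meg3 and Mirg. Strain bias was called for 551 genes, 309 toward 129S1 and 242 toward JF1.

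In homozygous placentas most noncanonical imprinted genes moved toward equal expression of the parental alleles. Of the measured genes of this list 5 of 7 passed at 6 somites with a 129S1 mother, 6 of 7 with a JF1 mother and 5 of 6 at 12 somites. The maternal share of Sfmbt2 rose from 0.590 ± 0.122% to 44.1 ± 4.62% at 6 somites with a 129S1 mother, from 0.292% to 33.8 ± 4.60% with a JF1 mother and from 0.584% to 27.5 ± 12.3% at 12 somites. In the same order, Smoc1 went from 14.6 ± 7.73% to 51.2 ± 1.06%, 20.1% to 46.6% and 22.2% to 48.5%. Gab1 went from 28.1 ± 5.13% to 49.8 ± 1.27%, 16.5% to 47.2% and 21.6% to 48%. Slc38a4 went from 0.985% to 28.3 ± 14.3%, 1.34% to 42.1 ± 4.52% and 1.78% to 35.6 ± 9.27%, and Jade1 moved from 21.2% to 54%, 9.51% to 44.8% and 13.7% to 45.3%. Over all genes Platr4 passed with a JF1 mother (23.7% to 47.8%), but not with a 129S1 mother (a rise of 22.8 points, adjusted p = 0.099) or at 12 somites (10.9 points, adjusted p = 0.84). Platr20 passed in neither 6-somite cross (27.1% to 66.4%, adjusted p = 0.051, and 4.03% to 29.5%, adjusted p = 0.2). With a 129S1 mother both passed on autosomes tested alone (Platr4 0.024, Platr20 0.014). Adjusted over the imprinted lists alone, both passed in both 6-somite crosses (Platr4 0.0029 and 0.00048, Platr20 0.0013 and 0.0069), and Platr4 did not at 12 somites (0.4). edgeR called a changed share (two-sided) for 67 of 11569, 70 of 11520 and 43 of 11977 genes, with 50, 55 and 31 moving toward the mother. On autosomes tested alone 118 passed in the first comparison and 90 in the last. Of paternal autosomal genes in controls, 37, 37 and 20 moved toward equal shares, but 30, 30 and 13 of these lie inside Sfmbt2 and 7 outside it each time. Some canonical imprinted genes also changed. Phlda2 went from 93.9% to 73.1%, 97.7% to 81.1% and 96.1% to 82%, and Slc22a18 from 84.1% to 69.6%, 98.8% to 84.5% and 95.4% to 77.5%. Ascl2 (97.2% to 82%) and Mirg (99.6% to 73.7%) changed with a 129S1 mother, while Igf2 (5.04% to 1.91% with a JF1 mother) and Meg3 (94% to 99.1% at 12 somites) moved further to 1 parent. Among genes outside the lists the largest changes were in RNAs inside Sfmbt2, such as Gm22925 (2.38% to 76.5%), Mir669j (0% to 61.3%) and Gm24673 (0% to 81.3% with a JF1 mother). Gm31266 inside Jade1 changed from 5.37% to 65.5%. At 12 somites the 5 largest were in Naa11 (87.4% to 43.5%), Nckap1l (9.75% to 52.1%), Gm23571 inside Sfmbt2 (2.27% to 40.6%), Sohlh2 (13.8% to 50.3%) and Gm23988 inside Sfmbt2 (0.5% to 35.8%). The panels per placenta show the noncanonical genes over all groups.

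**Figure D2:**
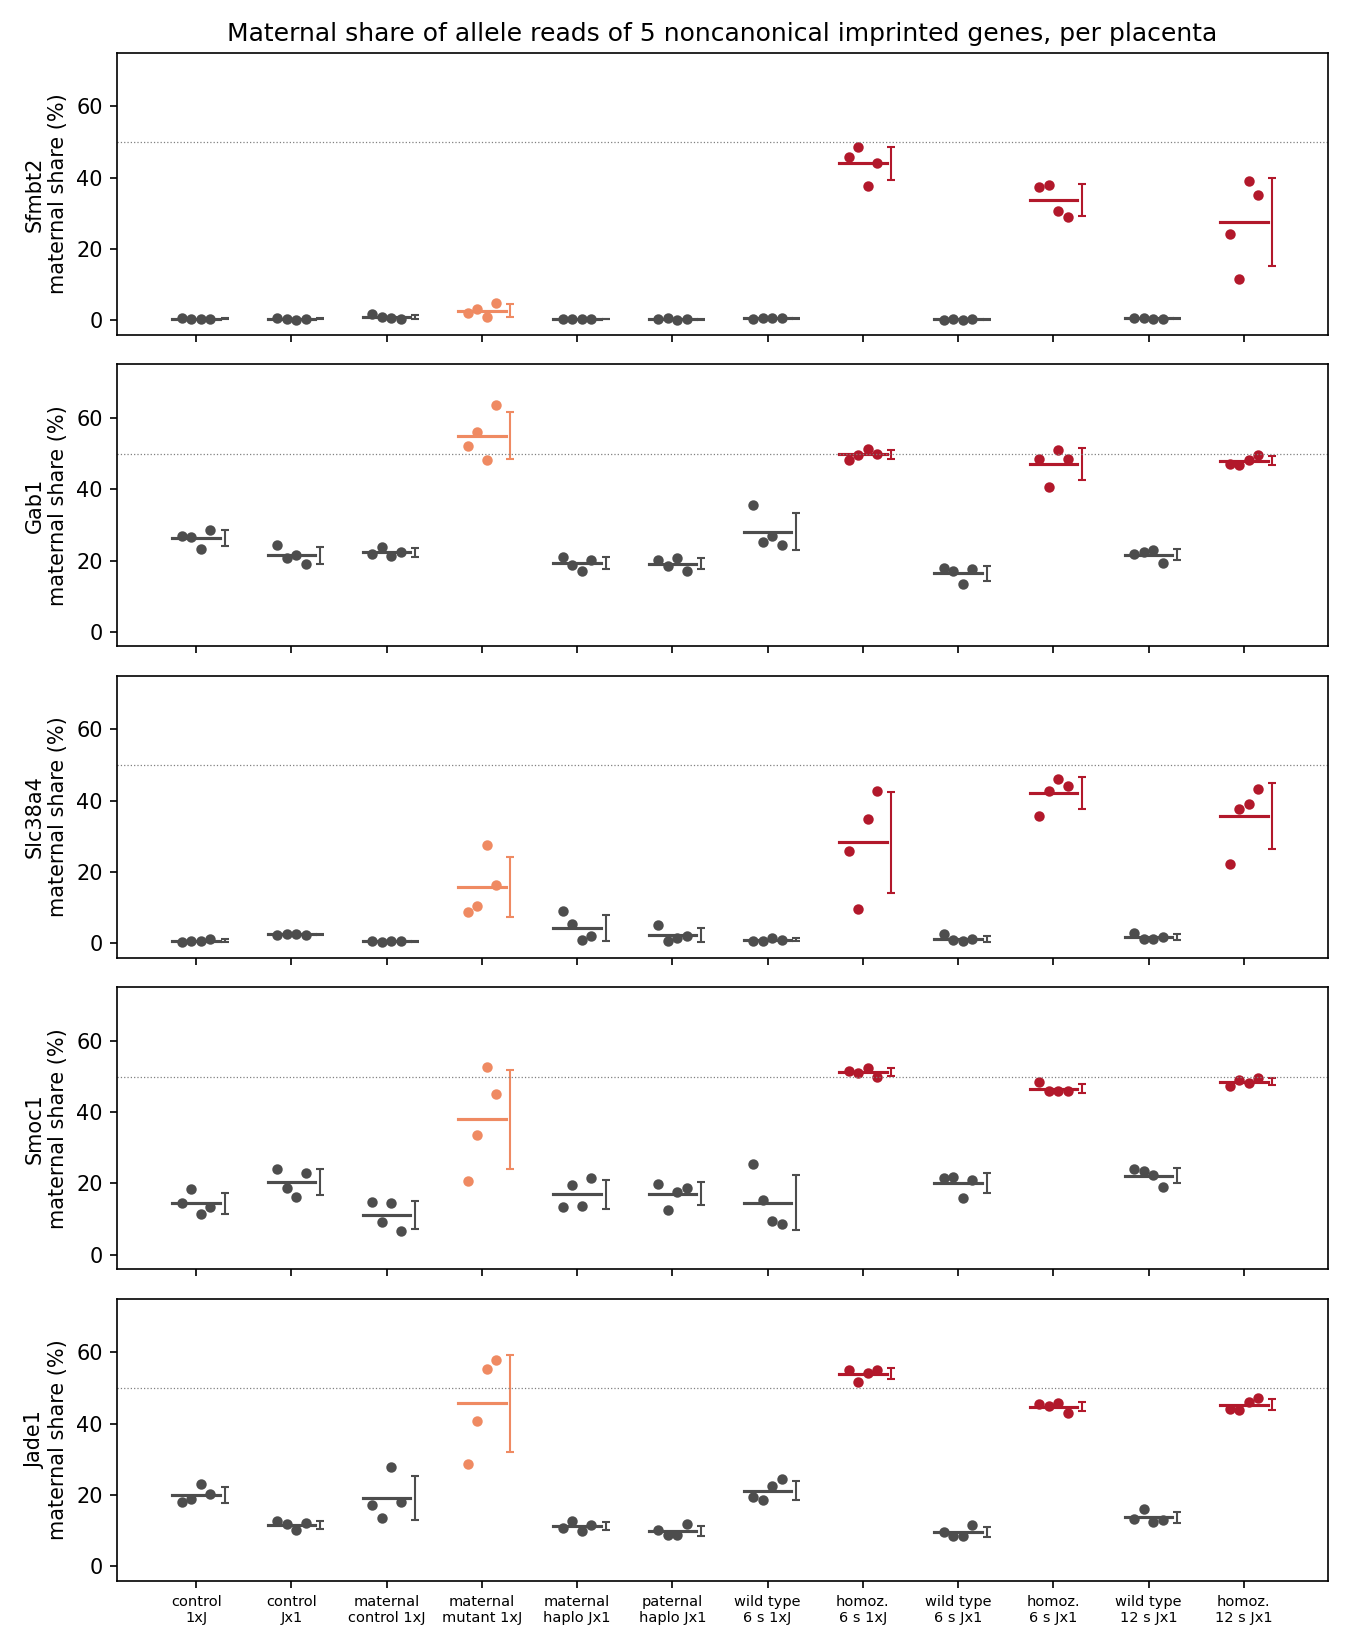
Maternal share of allele reads per placenta for Sfmbt2, Gab1, Slc38a4, Smoc1 and Jade1 in the 12 groups. The dotted line marks equal shares.

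Placentas from oocytes that lacked Ehmt2 differed widely among themselves. Per the labels, mutant replicate 1 was collected at the age of the controls and replicates 2 to 4 at a later age. The effects of age and of the oocyte deletion were not parted. Hbb-y (log2 9.36 ± 2.31), Hbb-bh1 (log2 7.94 ± 1.66) and the yolk-sac gene Afp (log2 7.18 ± 2.05) had higher means than in maternal controls. So did the decidual hormone gene Prl8a2 (log2 6.07 ± 1.58) and the giant-cell gene Prl2c3 (log2 5.00 ± 1.43), none past the threshold (adjusted p = 0.39). edgeR called 0 of 17797 genes (two-sided), with 2206 at an unadjusted p below 0.05, and DESeq2 called 42. With all 48 libraries in 1 fit, whose spread comes from all groups, edgeR called 3688. Adjusted over the list alone, 10 of 15 giant-cell genes were higher (camera 0.00019, and 0.547 with an estimated correlation). So were 8 of 12 parietal endoderm genes (1.6e-06, and 0.547 with an estimated correlation) and 4 of 8 erythroid genes. Decidua markers moved with the group, 9 of 16 higher adjusted over the list alone (2.1e-05, and 0.547 with an estimated correlation). So did maternal blood, 2 of 3 (0.0086, and 0.547), and natural killer markers, with a median log2 of 1.22 (0.0058, and 0.547). Visceral endoderm genes had a median of 2.04 (9.9e-06, and 0.547), allantois genes of 1.84 (0.00095, and 0.585) and endothelium genes of 1.49 (0.0047, and 0.547). Proliferation genes were lower, with a median of -0.298 (0.00026, and 0.585). Among allele shares, the 129S1 share of Gab1 rose from 22.3% to 55.1 ± 6.53% (adjusted p = 0.018) and that of Slc38a4 from 0.551% to 15.8 ± 8.44% (adjusted p = 3.4e-05). These were the 2 called of 11767. With shares centred on each library's median 0 were called. Without replicates 2 and 4, 21 were called. Gab1 did not pass without mutant replicate 2 or without any 1 control, which left Slc38a4 as the 1 gene called, and 7 were called without mutant replicate 1. Gab1 (chr8:80764434-80880479) lies where the median 129S1 share of chromosome 8 was 37.2% and 38.2% in replicates 2 and 4 and 50% in replicates 1 and 3, so in replicates 2 and 4 its 129S1 share need not be a maternal share. Per library in replicate order, Gab1 was at 52.2%, 56.2%, 48.3% and 63.6%, and Slc38a4 at 8.90%, 10.4%, 27.5% and 16.3%. Jade1 was at 28.7%, 40.8%, 55.3% and 57.9%, and Sfmbt2 at 1.95%, 3.15%, 0.841% and 4.92%. These are 129S1 shares, and single libraries held other segments with few 129S1 reads. Replicate 1 had a median of 8.02% on chromosome 3 from 35 to 40 Mb, beside Jade1 (chr3:41555731-41616864), and of 0.339% on chromosome 13 from 60 to 70 Mb. Replicate 3 had 0.247% on chromosome 2 from 115 to 125 Mb. In replicates 2 and 4 the median maternal share per gene was 67.8% and 68%, against 51% to 51.4% in the others, on most autosomes.

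**Figure D3:**
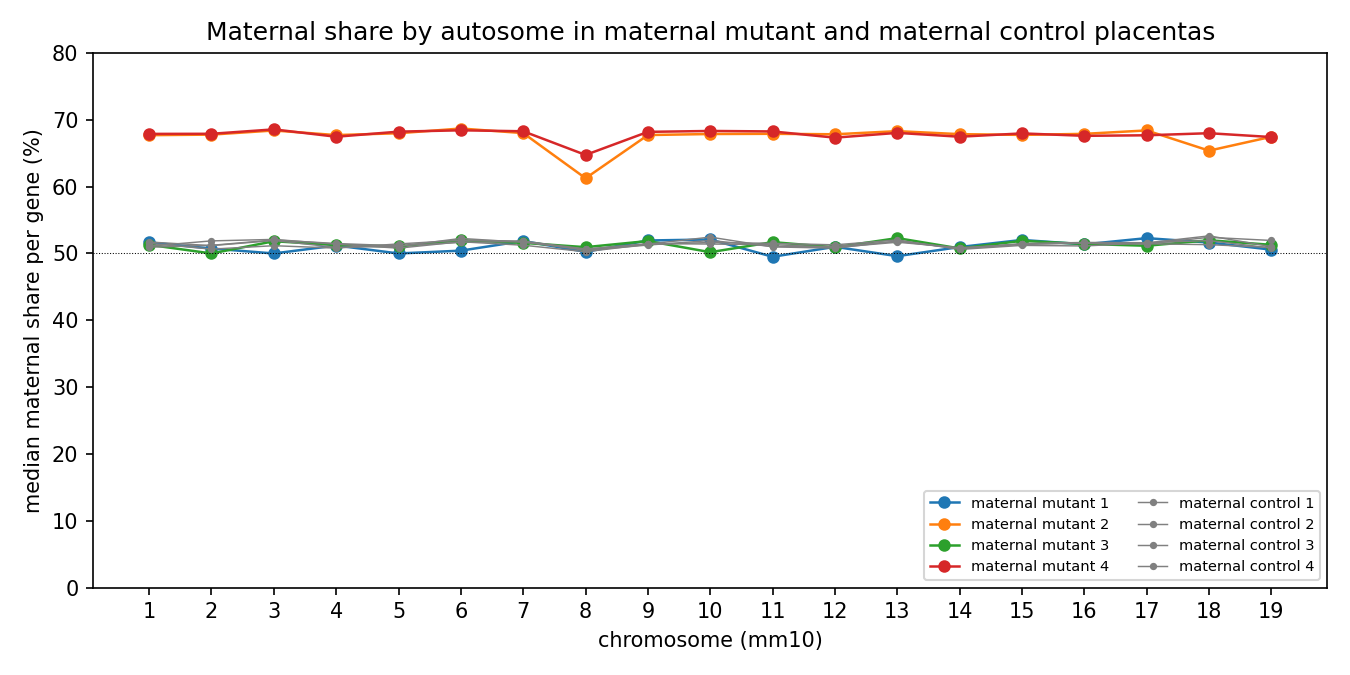
Median maternal share per gene by autosome in each maternal mutant and maternal control placenta.

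Wild-type placentas of a heterozygous father had less embryonic globin RNA than the control line. Hba-x (chr11:32276400-32278116) fell from 16.4 to 0.905 CPM (log2 -4.17 ± 0.40, adjusted p = 0.020) and Hbb-bh1 (chr7:103841636-103843164) from 21 to 1.86 CPM (log2 -3.50 ± 0.34, adjusted p = 0.020). These were the only 2 genes called of 17665 by edgeR (two-sided; 2960 at an unadjusted p below 0.05), where DESeq2 called 596. With the replicate block or with all libraries in 1 fit none was called. With 1 library left out, 0 were called without control 1 or 3 or the group's own replicate 2 or 4, 7 without its replicate 3 and 30 without control 4. Of 35 splits of these placentas 3, the real one included, called at least 2 genes, the highest of the others 14. Adjusted over the list alone, all 13 allantois genes were lower (camera 7.4e-09, and 0.516 with an estimated correlation). Of parietal endoderm genes 9 of 12 were lower and 1 higher (3.9e-05, and 0.192 with an estimated correlation). In turn 12 of 14 giant-cell genes were higher and 1 lower (2.1e-06, and 0.544 with an estimated correlation). Placentas of a heterozygous mother gave 0 calls of 17868 by edgeR, with 3006 at an unadjusted p below 0.05 and 339 by DESeq2. Adjusted over the list alone, 7 of 14 giant-cell genes (0.0086, and 0.888 with an estimated correlation) and 5 of 7 interferon genes were higher (0.00089, and 0.688 with an estimated correlation). No allele share changed in either group over all genes. On autosomes tested alone 8 did with a heterozygous mother and 5 with a heterozygous father. The globin falls with a heterozygous father rest on the control line as reference. Against the same control placentas the wild-type siblings of the next paragraph also had less Hba-x. Whether the difference lies in the control placentas was not tested.

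Wild-type siblings of the JF1-mother cross differed from the control line more than either of these groups. The placental protease genes Cts8 (0.411 to 62.1 CPM, log2 7.22 ± 1.22) and Cts7 (log2 7.13 ± 1.16) and the adhesion gene Ceacam15 (log2 7.17 ± 1.18) rose. So did Psg29 (6.32 to 362 CPM, log2 5.85 ± 1.11) and the hormone gene Prl4a1 (13.6 to 355 CPM, log2 4.71 ± 0.36), all in near-identical families. Hbb-y (log2 -4.88 ± 0.74), Hba-x (log2 -4.63 ± 0.74), the vessel peptide gene Apln (log2 -3.69 ± 0.66) and Slc13a4 (log2 -2.84 ± 0.55) fell. edgeR called 893 of 17616 genes (two-sided), 460 up and 433 down, and between 64 and 2582 when any 1 library was left out. Giant-cell genes rose in 12 of 14 cases (13 up and 1 down adjusted over the list alone). Camera gave an adjusted p of 3.6e-10, and 0.0308 with an estimated correlation. Of allantois genes 4 of 13 fell (12 adjusted over the list alone). The list as a whole passed at 4.5e-09 by camera, but lay at 0.332 with an estimated correlation. The comparisons with this control line share its placentas. Their fold changes correlated at 0.757, 0.754 and 0.871, where simulated unrelated groups with shared controls gave 0.501, 0.509 and 0.495. Siblings of the 129S1-mother cross gave 0 of 17818 (1267 at an unadjusted p below 0.05; DESeq2 11).

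Maternal controls of the floxed line differed from the 129S1-mother control line in 150 of 17612 genes (edgeR, two-sided), 120 up and 30 down. With the replicate block it was 368, with pairs by number inferred from correlations of same-numbered placentas (0.33, 0.18, 0.10 and 0.22). In only 2 pairs was the correlation highest with the own number. Sex runs with the numbers too, replicates 1 and 2 being female and 3 and 4 male in both groups. With all 48 libraries in 1 fit 0 were called, DESeq2 called 733, and with 1 library left out the count ran from 70 to 279. It was 85 without control replicate 2 and 71 without 4, and 98, 279, 95 and 70 without the group's own replicates 1 to 4. The histone genes Hist1h3a (log2 0.68 ± 0.06) and Hist1h2an (log2 0.72), of near-identical families, rose. So did the uridine phosphorylase gene Upp1 (26.1 to 53 CPM, log2 1.02 ± 0.14) and the signalling adaptor gene Card9, while Tnc (log2 -2.03 ± 0.37), Gramd1b (log2 -0.76 ± 0.09) and Dnmt3a (log2 -0.49 ± 0.09) fell. Visceral endoderm markers moved with this group, with a median log2 of -2.29 (1.2e-05, and 0.581 with an estimated correlation). The control lines of the 2 crosses differed in 850 of 17775 genes, 351 higher and 499 lower with a JF1 mother. Every count with 1 library left out was lower (283 to 593): 380, 302 and 283 without 129S1-mother replicates 1, 3 and 4, and 522, 361 and 551 without JF1-mother replicates 1, 3 and 4. All 48 libraries in 1 fit gave 207, the replicate block 212 and DESeq2 1431. Lncenc1 rose from 1.92 to 29.5 CPM (log2 3.95 ± 0.18) and the mitochondrial mt-Co2 (log2 2.42 ± 0.26) was higher. Lower were Xkrx (log2 -4.45 ± 0.42), the interferon-induced Rsad2 (log2 -2.26 ± 0.36), the fusion gene Syna (log2 -2.25 ± 0.52) and the imprinted Igf2r (log2 -1.02 ± 0.08), while its antisense transcript Airn was higher (log2 0.96 ± 0.12).

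The maternal share of all autosomal allele reads was 52.6 ± 0.643% in homozygous placentas of 129S1 mothers against 51.5 ± 0.213% in siblings (exact two-sided permutation p = 0.0286, 0.171 after adjustment, the smallest p that 4 against 4 can give). In this cross, paternal 129S1 reads of the chromosome 17 interval count as maternal in homozygous placentas. Without chromosome 17 genes from the interval to 46 Mb, which include the 3 rRNA-like genes, the difference of 1.14 points came to 0.219 (exact p = 0.0286), and without the 3 rRNA-like genes alone to 0.334. As a median over genes it was -0.003 (exact p = 1). Over all autosomal reads the difference was 0.685 points in the JF1-mother cross (exact p = 0.0857) and -0.226 at 12 somites (exact p = 0.171). It was 7.56 in maternal mutants (59.1 ± 9.48% against 51.6 ± 0.108%, exact p = 0.4), -0.0416 with a heterozygous mother (exact p = 0.914) and -0.280 with a heterozygous father (exact p = 0.457). The coefficient of variation between placentas was highest in maternal mutants, 0.358 against 0.128 in their controls. It was 0.196, 0.185 and 0.172 in the homozygous groups against 0.126, 0.198 and 0.152 in their siblings.

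Around Ehmt2, all 12 homozygous placentas carried 129S1 alleles almost alone in the interval stated in the labels (99.3% to 100% of allele reads, against 46.6% to 67.4% in the other 36 placentas). In the next 43 measured genes beyond it 6 of the 12 stayed above 90%, and in the 57 genes farther along none did. Inside the interval 10 of 40, 4 of 40 and 11 of 41 measured genes were called in the homozygous comparisons.

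**Figure D4:**
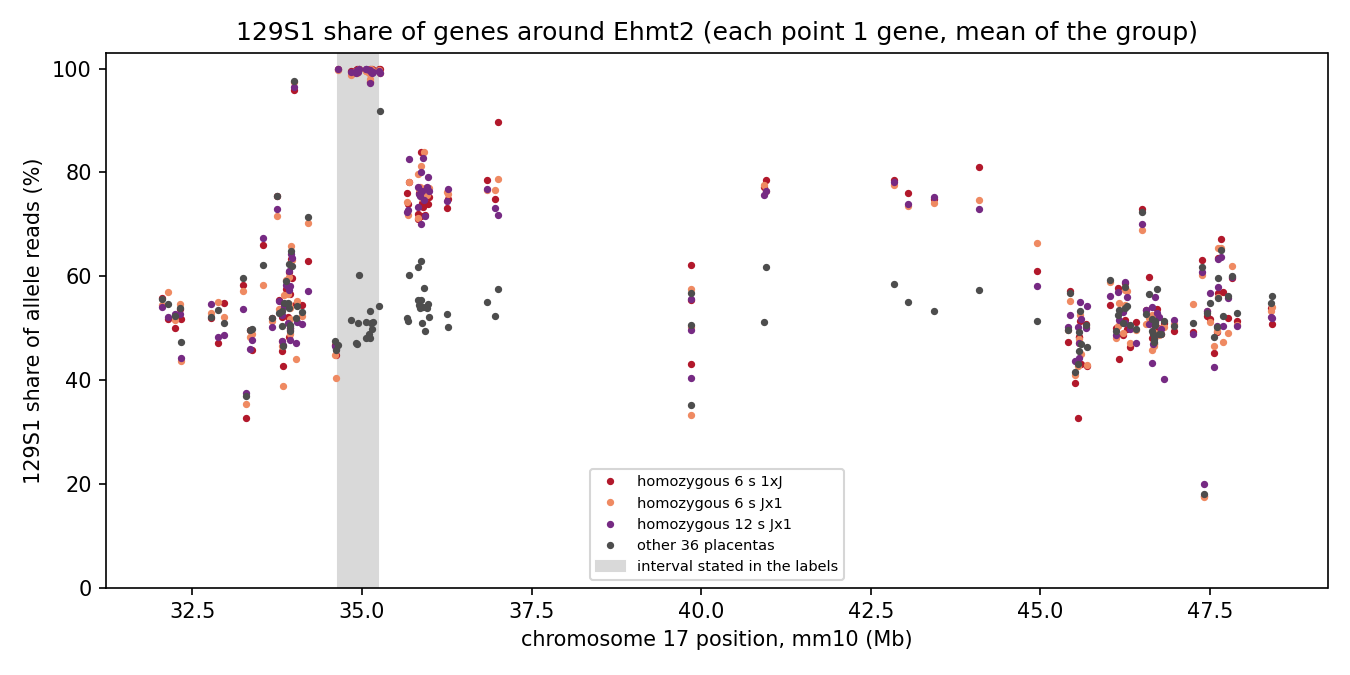
Share of 129S1 allele reads of genes around Ehmt2 in the homozygous groups and the other placentas, as group means per gene. The grey band is the stated interval.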

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

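The ectoplacental and chromosome 8 tests below were chosen only after the result was seen. Several measures were tested in each of the 12 groups of 4 placentas for a value far from the other 3. Of these 72 tests 7 found one, where chance gives about 1 in 20. In homozygous 6-somite placentas of the JF1-mother cross, replicate 1 had 27824050 counts against 22779327 to 23604933, and replicate 4 had 144.5136 CPM of Ehmt2 against 154 to 155 on CPM over total counts. On the TMM-scaled CPM of the report it had 144.8 against 155.8 to 159.2, no longer far enough for this test. Among wild-type 12-somite siblings, replicate 2 had 20.3% allele reads against 22.2% to 22.4%. It is the library of that group whose name carries a suffix, and all 5 libraries with the suffix had 20% to 20.3%, against 21.4% to 22.9% in the other 43. The rRNA-like share was 14.7% in replicate 3 of the 129S1-mother control line against 11.1% to 11.6%, and 11.8% in replicate 4 of the 12-somite homozygous group against 12.4% to 12.5%. Replicate 4 of the 129S1-mother wild-type siblings had 24475 detected genes against 26470 to 26840, and an autosomal maternal share of 51.15% against 51.5% to 51.6%. Each of these was a single value far from its own group. The homozygous effect differed between stages for 69 genes and between crosses for 519 genes, each by an interaction test in edgeR.

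Maternal mutant replicates 2 and 4 had nearly 2 maternal reads per paternal read. Maternal tissue in the dissection is excluded as the whole source, since trophoblast genes, which come from the embryo, shifted too, by at least 14.262 points over the highest maternal control. The gene-to-gene SD of the share was also at most 1.0626 times that of the controls, although decidua genes in replicate 4 stood 2.48 log2 units above controls. That replicate, a male, also had 322 CPM of Xist and 33.8 CPM of Ddx3y, where the other males of the study had 13.8 to 36 and 71 to 89.8 CPM, so some maternal tissue may be present there. An extra maternal genome set fits: the lower median share was 67.813%, and paternally expressed imprinted genes stayed at 3.52% and 5.50%. Such a set would also bring an X, so the Xist and Ddx3y values of replicate 4 do not part it from maternal tissue. On chromosome 8 from 65 to 95 Mb the median 129S1 share fell to at most 38.235%, which also fits if the mother carried a JF1 segment there, a test written after the values were seen.

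Wild-type siblings of the JF1-mother cross stood apart from the control line. An earlier developmental state fits for most genes also called between 12 and 6 somites in homozygous placentas, which share no library with this comparison. Of these 464 genes 98.922% moved oppositely. The giant-cell list, higher in these siblings, does not go with it in wild-type placentas. There 5 of 15 giant-cell genes rose from 6 to 12 somites and none fell (median log2 1.4974). In homozygous placentas 2 of 16 rose and none fell, with a median of -0.33097. More ectoplacental cone tissue in the dissection fits as well, with a median log2 of 2.8456 for that list, but on 6 of its 19 genes (3 called), at 0.00416 by camera and 0.478 with an estimated correlation. The design does not part the 2 explanations. A departure of the control line itself is also left open. Against it the median log2 of the giant-cell list was 2.73 in these siblings. It was 2.14 and 2.59 in placentas of a heterozygous mother and father. Between the control lines the giant-cell median was -2.62, lower in this one, while the allantois median was 0.0096. The ages in the labels also differ between the siblings and the control line, so the difference could be one of collection and not of parental genotype. Placentas of a heterozygous mother or father were collected at the labelled age of the control line. Labelled age thus does not explain the giant-cell rise in those groups.

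The 129S1 interval carried beside the mutant allele could have produced calls near Ehmt2 by strain alone. Interval genes were called at no more than 1.09 times the share of all genes, and at the least at 0.80583 times, so the interval was not enriched for calls. With 40 or 41 measured genes this does not exclude a strain effect on some of them. Of those called, 6 of 10, 3 of 4 and 10 of 11 fell in the 3 homozygous comparisons. The 129S1 segment beyond the interval was not tested in this way.

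Other splits of the same placentas test whether chance can be excluded (real count, then the highest of the others, with the number of splits at least as large including the real one). Over 35 splits, the mark was met by homozygous placentas of the 129S1-mother cross (4159, 167, 1), the JF1-mother cross (2212, 7, 1) and 12 somites (5802, 8, 1). The split with 167 parts the sexes, and in that cross the females are also the libraries whose names carry a suffix. Chance is also excluded for JF1-mother siblings against controls (893, 376, 1), stages in wild-type (2460, 8, 1) and homozygous placentas (4993, 13, 1), and the control crosses (850, 12, 1). Over 50 splits the mark was met by the interactions by stage (69, 0, 1) and by cross (519, 53, 1). Parent-of-origin bias met it over 35 splits (509, 1, 1), and strain bias over 61 (551, 6, 1). The 509 include 371 X-linked and 26 mitochondrial genes, whose bias the design sets. The 112 autosomal calls were not split alone. Chance is not excluded for embryos of a heterozygous father (2, 14, 3). For maternal mutants (0, 4, 35), embryos of a heterozygous mother (0, 125, 35) and 129S1-mother siblings (0, 20, 35) the splits say nothing on chance, since any count is at least as large as 0.

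For changes of allele share with X-linked genes included, a split by sex called more genes than the real one: 195 against 67, 92 against 70 and 294 against 43 in the homozygous comparisons (2 of 35 splits each), and 254 against 2 in maternal mutants (3 of 35). Chance is not excluded by these counts. For embryos of a heterozygous mother (250 against 0, 35 of 35) and father (199 against 0, 35 of 35) the real count of 0 makes the test void. The split by sex points to a structure of the samples, since males carry only a maternal X. On autosomes alone the homozygous comparisons met the mark of a share under 0.05, each with 1 split of 35. The real counts were 118 and 90 in the 129S1-mother cross and at 12 somites against 6 and 1. In the JF1-mother cross at 6 somites the highest other was 2. In maternal mutants it was 5 against 2, also 1 split of 35 (Slc38a4, Gab1, Peg3, Smoc1 and Zfp473, the last chosen after its values were seen). There the real grouping carries the library-wide shift of replicates 2 and 4, and centred shares gave 0 calls. The splits thus do not settle changes of single genes in maternal mutants. For maternal controls against controls, pairs by number were inferred from correlations. There 8 splits part the 4 pairs, too few for a share under 0.05. The count was 150 against 1 in the highest other of these, or 368 against 0 with the replicate block. Splits that part fewer pairs called up to 50.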

How the results depend on the processing

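The control-line, male-only, reduced-library, centred and chromosome 17 settings were chosen after seeing the data. Most results kept their direction and their side of the threshold. Of 5670 values for named genes under alternatives, 5240 were the same, 426 were weaker and 4 reversed; with a library left out, 5565 of 6632 were the same, 1061 were weaker and 6 reversed. Genes called in the reported test and in an alternative never changed sign (0 of 304481). Genes past the threshold in both fits of the same counts could hardly do so, so this says little on robustness. For every count below the cause was not tested, except where fewer genes or samples enter by construction.

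With DESeq2, adjusted p below 0.05 was reached by 42 genes in maternal mutants, 339 with a heterozygous mother, 596 with a heterozygous father, 11 and 1813 in wild-type siblings of 129S1 and JF1 mothers, 733 in maternal controls, 1431 between control crosses, and 522 and 1064 in the interactions by stage and cross. Without a filter edgeR called 35 with a heterozygous father and 321 in maternal controls. With all 48 libraries in one fit it called 4391 in homozygous 6-somite placentas of JF1 mothers, 3688 in maternal mutants, 0 with a heterozygous father, 519 in JF1-mother siblings, 0 in maternal controls and 207 between crosses. Sex as a covariate gave 561 in JF1-mother siblings. Males alone gave 1746 in the 129S1-mother homozygous comparison (fewer samples), and the control line as reference 5874 with a JF1 mother. Without replicates 2 and 4, maternal mutants gave 5.

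With the replicate block, counts were 900 (homozygous, JF1 mother), 0 (heterozygous father), 543 (JF1-mother siblings), 368 (maternal controls), 212 (control crosses), 29 and 330 (interactions), and for allele share 261, 158 and 175 (homozygous) and 21 (maternal mutants).

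Share changes on autosomes alone numbered 118 (129S1 mother), 90 (12 somites), 5 (maternal mutants), 8 (heterozygous mother) and 5 (heterozygous father). Autosomal parent-of-origin calls numbered 112, as X-linked and mitochondrial genes are left out. At 50 reads or more 44 share changes (129S1 mother) and 326 strain calls remained. In maternal mutants centred logit shares gave 0 and leaving out replicates 2 and 4 gave 21. With an estimated correlation 4 of 390 list tests passed, against 136 at the preset one.

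Without chromosome 17 genes from the interval to 46 Mb the difference in maternal share turned to 0.0859 points at 12 somites. As a median over genes, it was -0.00300 (homozygous, 129S1 mother), 0.0327 (heterozygous mother) and 0.0768 points (heterozygous father). It also turned with a heterozygous mother without control replicate 1 (0.182) or 3 (0.0754), or without the group's own replicate 1 (0.0641). Ehmt2 was not called and turned sign in 4 comparisons with a library left out: it ran from -0.0435 (wild-type 3 out) to 0.0139 (wild-type 1 out; also above 0 with homozygous 3 out) in the 129S1-mother homozygous comparison, from -0.1169 (own 2 out) to 0.0186 (own 1 out) with a heterozygous mother, from -0.0793 (own 2 out) to 0.024 (control 2 out) with a heterozygous father, and from -0.042 (sibling 1 out) to 0.0137 (sibling 3 out; also above 0 with control 3 out) in 129S1-mother siblings. Against the control line Hba-x (-0.62), Oas1a (0.30) and Slc43a2 (-0.25) turned in JF1-mother homozygous placentas, and Pon3 (0.11) in the interaction by cross. At log2 CPM of 3 or more the variation was 0.111 and 0.109 (129S1-mother and maternal controls), 0.157 and 0.169 (heterozygous mother and father), 0.164 and 0.164 (homozygous 6 somites) and 0.104 (129S1-mother siblings).

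With each library left out, counts ran from 3024 to 4842, 1373 to 2183 and 4822 to 5840 in the homozygous comparisons, 0 to 1 in maternal mutants, 0 to 1 and 0 to 30 with a heterozygous mother and father, 0 to 0 and 64 to 2582 in siblings, 70 to 279 in maternal controls, 1563 to 2972 and 3394 to 5469 by stage, 283 to 593 by cross, and 6 to 160 and 207 to 648 in the interactions. Share changes ran from 58 to 68, 58 to 67, 26 to 46, 1 to 7, 0 to 0 and 0 to 0, parent-of-origin calls from 503 to 511 and strain calls from 545 to 560. Maternal share ran from 0.875 to 1.33, 0.580 to 0.904, -0.341 to -0.120, 4.82 to 10.5, -0.289 to 0.182 and -0.528 to -0.0574 points. No difference passed after adjustment. Before it, the exact p of the first rose above 0.05 without any 1 wild-type library (1.18, 1.19, 1.17 and 1.04), and that of the second fell below it without wild-type replicate 3 (0.904). Variation ran from 0.108 to 0.135 and 0.117 to 0.165 (control lines), 0.152 to 0.192 and 0.184 to 0.201 (heterozygous mother and father), 0.263 to 0.413 and 0.116 to 0.137 (maternal mutants and controls), 0.157 to 0.220, 0.167 to 0.202 and 0.132 to 0.193 (homozygous) and 0.112 to 0.135, 0.129 to 0.218 and 0.133 to 0.165 (siblings).

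Single libraries moved counts most as follows. JF1-mother homozygous: replicate 3 out, 1373. Maternal mutants: mutant 4 or control 2 out, 1. Heterozygous mother: control 4 or own 2 out, 1. Heterozygous father: control 4 out, 30, own 3 out, 7, and control 1 or 3 or own 2 or 4 out, 0. JF1-mother siblings: control 1 (119) or 3 (64), sibling 2 (248), 3 (2582) or 4 (300). Maternal controls: control 2 (85) or 4 (71), own 1 (98), 2 (279), 3 (95) or 4 (70). Wild-type stages: 12-somite 4 (1563). Control crosses: 129S1-mother 1 (380), 3 (302) or 4 (283), JF1-mother 1 (522), 3 (361) or 4 (551). Stage interaction: 12-somite homozygous 1 to 4 (44, 30, 22, 43), 6-somite homozygous 2 to 4 (131, 33, 26), 12-somite wild type 1 to 4 (45, 6, 26, 11), 6-somite wild type 1 to 3 (31, 23, 160). Cross interaction: 129S1-mother homozygous 1 (309) or 3 (243), JF1-mother homozygous 3 (249), 129S1-mother wild type 1 to 3 (207, 212, 329), JF1-mother wild type 2 (301). Share at 12 somites: homozygous 1 (28), wild type 3 (28) or 4 (26). Share in maternal mutants: mutant 1 (7) or 2 (1), or any control (1).

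Small changes are often missed at this depth and spread, whose parts were not tested separately: at 1.5-fold, 28.4% of simulated changes were recovered in the 129S1-mother homozygous comparison and 2.99% in maternal mutants.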

Other observations

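The genes of the next paragraphs, and the test on them, were chosen only after their values were seen. In homozygous placentas 47 autosomal genes changed their allele share in the 6-somite tests of both crosses (edgeR, two-sided), 30 of them inside Sfmbt2. Of the 47, 40 moved toward the same parent and 7 toward the same strain, whichever parent gave it. Nckap1l (chr15:103453825-103498800), a haematopoietic actin regulator, went from 98.4% to 54.5% 129S1 with a 129S1 mother. It went from 92% to 49.6% with a JF1 mother and from 90.2% to 47.9% at 12 somites. Its JF1 allele, low but not silent in the JF1-mother wild types, rose (0.0339 to 3.14 CPM). The level of Nckap1l rose too (log2 1.71 ± 0.16, 1.62 ± 0.18 and 1.94 ± 0.23). The germ-cell regulator Sohlh2 (chr3:55182028-55209957) went from 63.9% to 49.4%, 89.6% to 51.2% and 86.2% to 49.7%, with gains of log2 4.51, 2.23 and 3.13. Rnf17 (chr14:56402697-56525032), of the piRNA pathway, went from 84.8% to 68.6% and 84.2% to 65.3%, and at 12 somites did not pass (75% to 64.2%, adjusted p = 0.27).

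In other genes the share of 1 allele fell. Miip (chr4:147860778-147868816), which lies next to Fv1, went from 39% to 2.52%, 34.5% to 3.50% and 37.9% to 4.28% 129S1, its 129S1 allele dropping from 2.02 to 0.0894 CPM while the JF1 allele stayed at 3.22 and 3.17 CPM. The level of Miip fell in each group (log2 -0.68, -1.55 and -1.04). Nol7 (chr13:43398376-43402858), of the nucleolus, went from 42.6% to 17.9%, 43.7% to 21.9% and 42.7% to 16.5%, its 129S1 allele dropping from 10.4 to 2.38 CPM. Sec24d (chr3:123267455-123365641), of vesicle transport, went from 62.7% to 79.1% and 65% to 79.8%, but at 12 somites did not pass (adjusted p = 0.56). A strain segment inherited along with the mutant allele could have produced such shifts. For these 6 genes the median share of neighbours within 1 Mb moved by at most 3.12 points. This argues against a segment over most of that window. A segment over only the gene or a few genes would not move the median, so it is not excluded. The last of the 7, H2-D1 (chr17:35262730-35267499), lies just beyond the stated interval and went to 100%, 99.2% and 99.2% 129S1.

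Sall1 (chr8:89027248-89044162), which is in no imprinted list here, had a maternal share of 27.1% and 14.9% in the control crosses and was also chosen after its values were seen. Its share went from 28% to 53.3% (adjusted p = 0.0031), 11.8% to 36.1% (0.000147) and 21.6% to 35.7% (0.0076) in the homozygous comparisons, the same direction as the noncanonical genes.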
